A study of Mus musculus with 6 samples.

How the data were processed

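The series holds 6 ATAC-seq libraries of mouse intestinal organoids, 2 each of vehicle, 25 µM arachidonic acid (AA) and 50 nM prostaglandin E2 (PGE2) after 3 days. Per the labels' protocols, intestinal epithelial cells were sorted from the organoids before an Omni-ATAC reaction. The sort would remove most cells of other types.

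The values are raw counts per consensus peak, deposited by the authors as 1 table for all libraries. Per the file headers, featureCounts 1.6.3 counted read pairs in paired mode, with reads reduced to their 5′ ends, with a pair that overlapped several peaks counted in each and with no strand setting. Per the submitters' processing notes, the tools also included Trim Galore, BWA, Picard, SAMtools and MACS2, with build mm10; their settings are not given in the sources used here. Whether reads were shifted for the transposase's offset is not given there either; such a shift is small against peaks of a median 547 bp (175 to 3966). Because 1 set of peaks served all libraries, a region open in only 1 group could be counted in all, and a region in no peak was not measured. The 90823 peaks lay on 21 chromosomes. Totals were 12374232 to 14236985 counts per library, and the 100 peaks with the most counts took 1.37% to 1.42% of them.

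Each column was matched to its library by the label it carries. Peaks were given gene names with a gene table of assembly GRCm38.p6, the assembly of mm10. That table carried no strand here, so transcription start sites were not used, and the start site in the planned rule was replaced by either end of a gene. A peak was assigned to the protein-coding gene with the nearest end within 50 kb of its centre, which named 72409 peaks (79.7%) at 16862 of 21887 genes. A gene-end peak lay within 1 kb of either annotated end of a protein-coding gene (16297 peaks, 17.9%), and so takes in promoters and transcript ends alike. Of all peaks 56% lay inside a gene. Exons, introns and UTRs were not used here. The nearest gene need not be the one that a peak regulates.

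The main test was edgeR's (4.0.16) quasi-likelihood F-test with robust fitting on counts scaled by TMM (factors 0.969 to 1.02), after filterByExpr removed 1476 peaks and left 89347. All 6 libraries entered 1 fit with group as its term, which left 3 residual degrees of freedom. The estimate of spread also borrowed across peaks, with a median of 42.3 prior degrees of freedom. Each comparison was a contrast of that fit, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 changes are those implied by the F statistic. The median biological coefficient of variation was 4.4%, a low value that leaves open whether the 2 libraries of a group were technical repeats. CPM were computed from the TMM-scaled totals. Peaks with few reads had larger standard errors.

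The 21 gene lists were tested with camera in limma (3.58.1) on log2 CPM from voom, with a preset correlation of 0.01 and adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Camera tests a list against the other peaks and fry tests it against no change, so their p-values answer different questions. With the preset correlation camera measures spread over peaks rather than between libraries, so its p-values are not limited by the few libraries. With an estimated correlation camera has no more degrees of freedom than the fit (3). Its larger p-values therefore do not by themselves show that the peaks of a list move together. The lists covered intestinal stem cell genes, fetal and regenerative genes, YAP and TEAD targets, Wnt targets, cAMP and CREB targets, eicosanoid genes, PPAR targets, sterol and fatty acid synthesis, secretory and absorptive cell types, proliferation, immediate early, NF-kB, interferon and identity genes, and markers of stromal, immune and endothelial cells. Of the listed names 5 were not matched. Some genes were in several lists, such as Fabp1 and Fabp2 in the PPAR and the enterocyte lists, so the list results are not independent. The lists, the tests and most of the other settings below were fixed before the data were examined. Of 63 list results, 15 had a median or mean whose sign was opposite to that of the test, and 0 of these passed the threshold.

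Peaks were named by a rule. For each comparison it took the 8 largest changes in each direction among called peaks with an average log2 CPM of at least 1, with no overlap between the groups' libraries and with a gene within 50 kb, 1 peak per gene. It added the 4 gene-end peaks with the smallest p in each direction. It added the 3 members with the smallest p from every list that passed and, in any case, from the stem cell, fetal, YAP, Wnt, CREB and eicosanoid lists. Some peaks that the rule named are not reported here. Counts of peaks per gene, and the values of Lgr5 and Clu, were chosen after their values were seen. With 2 libraries against 2, no overlap of the groups arises by chance at 33.3% of peaks. It held for 100% of the called ones, which a small p nearly requires, so it adds no support to the calls.

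On simulated counts with 200 changed peaks among the 89347, the test recovered 83.3%, 77.6% and 81.6% of 3-fold changes and 69.4%, 75.5% and 71.4% of 2-fold changes for AA versus vehicle, PGE2 versus vehicle and AA versus PGE2. It recovered 28%, 22% and 22% of 1.5-fold changes. It made 10, 9 and 7 false calls among 88600, 88609 and 88596 unchanged peaks. The simulated counts took their spread from the data's own estimate, the same for all groups. The few false calls therefore do not test whether that estimate is too small. In the data 30.5%, 24.9% and 9.9% of the peaks were called, for which the adjustment is less strict. The simulated rates are therefore not the sensitivity of the results below. The overlap of the treatments was set beside 10 simulations of unchanged groups and beside independent lists. In the simulations all libraries, vehicle included, were drawn anew, and both treatments shared the simulated controls. Shares of gene-end peaks were tested with Fisher's exact test, two-sided.

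The alternatives were other scalings (DESeq2 size factors, library totals, loess offsets), DESeq2 (1.42.0) and limma-voom as other tests, other filters and thresholds, only the 4 libraries compared, a replicate block, autosomes only, other windows for gene assignment and gene ends, and each library left out in turn. Chosen after seeing the data were a separate scaling of gene-end and other peaks, fits without gene-end peaks, loess offsets for the lists, assignment by gene span and a fit with the vehicle libraries as separate groups, 1 for each treatment in both arrangements. Motif tests and corrections for base composition need a genome sequence and were not run. R was version 4.3.3; figures were drawn with Python 3.11.15 and matplotlib 3.10.9.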

Results

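Open chromatin was measured by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in mouse intestinal organoids, epithelial cultures that form crypt-like structures. The organoids received vehicle, 25 µM arachidonic acid (AA), a polyunsaturated fatty acid from which cells make prostaglandins, or 50 nM prostaglandin E2 (PGE2) for 3 days. The design text calls the prostaglandin a dimethyl analogue and the protocol calls it PGE2, so the exact compound is left as labelled. Each of the 3 groups had 2 libraries, and the labels do not say whether these came from separate cultures. The edgeR p-values of single peaks therefore measure only the spread between these libraries, pooled in part across peaks, which may be technical. Camera's p-values with the preset correlation measure spread over peaks, so a small one is not evidence over separate cultures either. Counts over 90823 consensus peaks (mouse build mm10) came to 12819432 and 12900551 in the vehicle libraries, 14236985 and 12374232 with AA and 13051109 and 13378895 with PGE2. The median peak held 57 to 66 reads per library. The libraries of a group differed by more than counting noise (chi-square per degree of freedom 1.1 for vehicle, 1.12 for AA and 1.56 for PGE2) and each counted as 1 replicate. Across peaks, log2 CPM (counts scaled to the size of the library) correlated at 0.981 to 0.982 within groups, and on average at 0.94 between vehicle and AA, 0.954 between vehicle and PGE2 and 0.971 between AA and PGE2. The first principal component held 54% of the variance, with vehicle at one end, AA at the other and PGE2 between them.

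The first comparison asked which regulatory regions of the epithelium opened or closed under AA. Peaks of the fetal and regenerative list, genes known from fetal gut epithelium and from repair after injury, were higher with AA than other peaks were. Of 163 tested peaks at 24 of its genes, 69 were called higher and 7 lower (70 and 7 when adjusted over the list alone), with a mean log2 change of 0.40 and an SD over peaks of 0.66. The list passed camera with the preset correlation (Benjamini-Hochberg adjusted p = 5.52e-09), and had adjusted p = 0.0783 with an estimated correlation. At 16 of its genes the called peaks were all higher. A peak 2288 bp from an end of Msln, which encodes the surface protein mesothelin (chromosome 17, 25755948 to 25757384, outside genes), rose 5.38-fold, from 3.48 ± 0.26 to 18.8 ± 0.78 CPM (mean ± SD, n = 2), a log2 change of 2.43 with a standard error (SE) of 0.15. A peak near Il1rn, which encodes an interleukin receptor antagonist (chromosome 2, 24316878 to 24317606), rose 4.1-fold (log2 2.03, SE 0.13). The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p-values of 9.31e-17 and 4.99e-16 for these peaks. Within the list 8 of 11 peaks of Anxa1, 7 of 9 of Ereg, 6 of 8 of Il1rn and 2 of 3 of Ly6a, the gene of the surface antigen Sca-1, were higher. The 3 peaks of Clu, a marker of regenerating crypts, had a median log2 change of -0.11, and 0 of them passed edgeR, DESeq2 or an unadjusted p under 0.05.

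**Figure D1:**
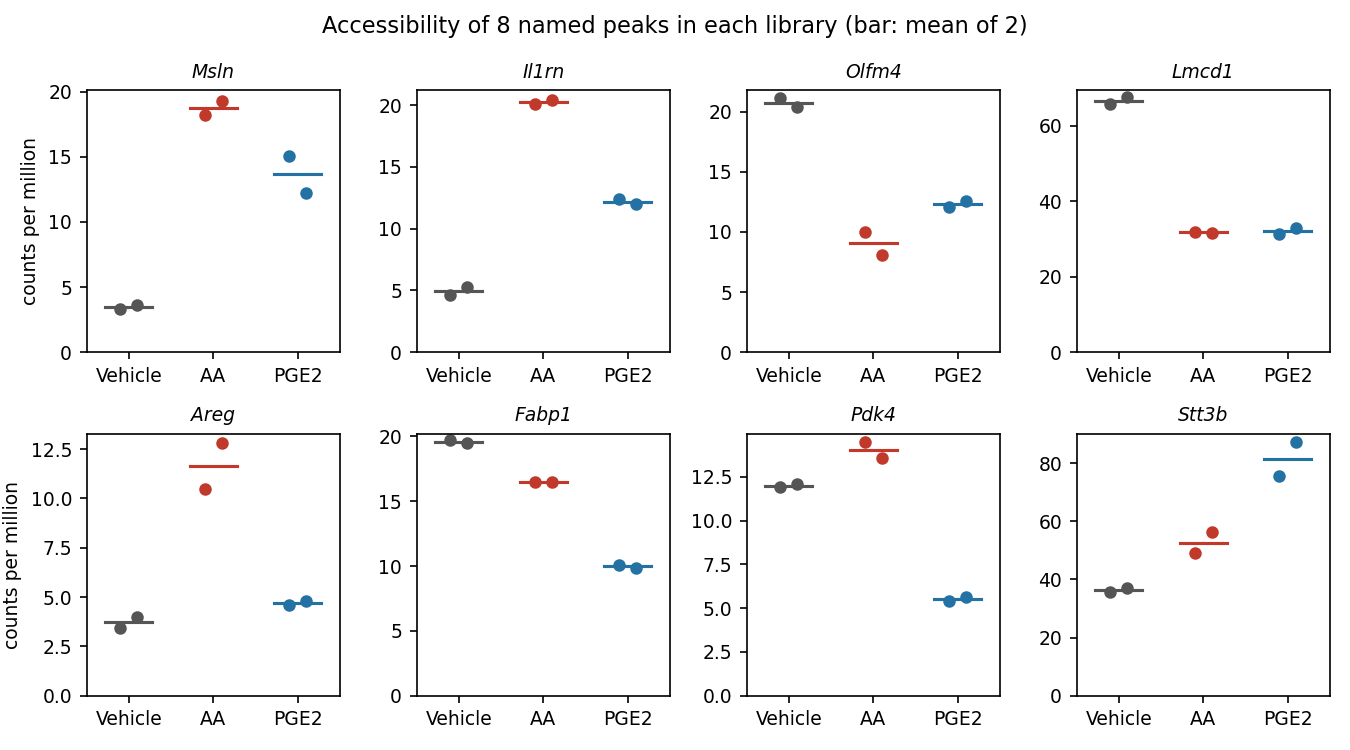
Normalised ATAC-seq signal (CPM, y axis from 0) at 1 peak each of 8 genes, by group on the x axis. Points are libraries and short lines are means of the 2 libraries of a group. At Msln both AA and both PGE2 libraries lie above the vehicle mean of 3.48, and at Pdk4 the PGE2 mean of 5.53 lies below the AA mean of 14.1.

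Peaks of the crypt stem cell list moved both ways under AA, with 62 lower and 34 higher of 261 at 22 genes (68 and 36 when adjusted over the list alone). The list did not pass camera (adjusted p = 0.0524). It passed fry, which tests against no change and not against other peaks (adjusted p = 0.0102, lower). At Olfm4, a marker of crypt base stem cells, 7 of 8 peaks were lower, and the one at chromosome 14, 79981283 to 79982034, fell 2.28-fold (log2 -1.19, SE 0.11; adjusted p = 3.72e-11, edgeR). A peak inside the water channel gene Aqp4 fell 2.31-fold (log2 -1.21, SE 0.12) and a peak 47856 bp from Sox9, a crypt transcription factor, fell 1.76-fold (log2 -0.81, SE 0.08). Sox9 had 1 peak higher and 1 lower of 9. Smoc2 had 8 of 14 peaks lower, while Cdk6 had 8 of 18 and Cd44 6 of 15 peaks higher. The 6 peaks of Lgr5, the receptor used to mark these stem cells, had a median log2 change of -0.09, and 0 passed edgeR, DESeq2 or an unadjusted p under 0.05.

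Among YAP and TEAD targets 40 peaks were higher and 21 lower with AA of 163 (adjusted p = 0.428, camera; 40 and 23 when adjusted over the list alone). This list passed fry, the test against no change (adjusted p = 0.0102, higher). Areg, an epidermal growth factor receptor ligand, gained 3.12-fold at a peak 944 bp from its end (log2 1.64, SE 0.16), Asap1 gained at a peak inside the gene (log2 0.86, SE 0.09) and Crim1 lost signal 48453 bp away (log2 -0.57, SE 0.07). Wnt and beta-catenin targets had 28 peaks higher and 25 lower of 185 (27 and 25 over the list alone; adjusted p = 0.805), among them Ccnd1, a cyclin of the cell cycle (log2 0.80, SE 0.08), and Cd44 (log2 0.63, SE 0.08). The cAMP and CREB targets had 25 higher and 22 lower of 124 (25 and 23 over the list alone; adjusted p = 0.805), with Crem at log2 1.39 (SE 0.2) and Fos at -0.92 (SE 0.14). Of the eicosanoid synthesis and receptor genes 28 peaks were higher and 21 lower of 169 (28 and 21 over the list alone; adjusted p = 0.875). These included the prostaglandin exporter gene Abcc4 (log2 1.22, SE 0.11), the leukotriene enzyme gene Lta4h (log2 0.78, SE 0.07) and the prostaglandin synthase gene Ptgs2 (log2 1.23, SE 0.17), which had 3 of 5 peaks higher. Not all peaks of these genes moved alike: Asap1 had 1 peak higher and 1 lower of 5, and Abcc4 5 and 1 of 27. All of these named peaks passed edgeR's test, with adjusted p-values from 5e-12 for Abcc4 to 1.72e-06 for Fos.

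None of the other lists passed camera under AA. Of these, enteroendocrine and stromal genes passed fry, the test against no change, both lower (adjusted p = 0.0174 and 0.0497). Counts of peaks higher and lower were 29 and 28 of 144 for PPAR targets and fatty acid oxidation (adjusted p = 0.85), 24 and 24 of 181 for sterol and fatty acid synthesis (0.805) and 25 and 26 of 148 for absorptive enterocyte genes (0.689). They were 3 and 11 of 43 for Paneth cells (0.0685), 19 and 18 of 114 for goblet cells (0.87), 5 and 8 of 58 for enteroendocrine cells (0.306) and 4 and 9 of 51 for tuft cells (0.428). Proliferation genes had 8 and 2 of 51 (0.805), immediate early and AP-1 genes 32 and 24 of 143 (0.805), NF-kB and epithelial defence genes 15 and 11 of 83 (0.805), interferon and antigen presentation genes 8 and 10 of 59 (0.805), and intestinal identity transcription factors 32 and 37 of 195 (0.85). Markers of other cell types had 2 and 5 of 36 peaks for fibroblasts and stroma (0.306), 2 and 4 of 18 for immune cells (0.805) and 7 and 8 of 51 for endothelial cells (0.805), in libraries made from sorted epithelial cells. Adjusted over the list alone, these 15 lists gave 29 and 30, 23 and 23, 25 and 29, 3 and 11, 20 and 19, 4 and 7, 4 and 9, 7 and 1, 35 and 24, 16 and 11, 8 and 10, 32 and 37, 2 and 3, 2 and 4, and 7 and 8 in the same order.

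Over all 89347 tested peaks, 14911 were higher and 12370 lower with AA (30.5% of the peaks; edgeR quasi-likelihood, adjusted p under 0.05), with median log2 changes of 0.73 and -0.64. With library totals as the scaling the larger side turned (13732 higher and 14316 lower). Changes of at least 2-fold were seen at 4796 higher and 2396 lower peaks. The largest gains lay near Tsc22d2 (6.7-fold, log2 2.74, SE 0.25), Egfr, the epidermal growth factor receptor (6.68-fold, SE 0.22), Col28a1 (6.59-fold, SE 0.21), the transcription factor Runx2 (6.57-fold, SE 0.32), Prkg2, Corin, Prss47 and 2310022A10Rik (5.67-fold, SE 0.31). They started from low signal, with vehicle means from 0.535 CPM for Prss47 to 1.49 CPM for Col28a1. The largest losses lay near 4933436I01Rik (log2 -2.37, SE 0.31), Gsc, Ei24 and Adamts18 (log2 -1.85, SE 0.25). Others lay inside F13a1, a coagulation factor chain (log2 -2.04, SE 0.19), Btbd11 (log2 -2.02, SE 0.24) and Emid1, and inside Gm5724 (log2 -2.29, SE 0.2), where similar gene copies leave the read placement uncertain. Among gene-end peaks, those within 1 kb of either annotated end of a protein-coding gene, Isx, an intestine-specific homeobox gene, rose 1.83-fold (log2 0.87, SE 0.07), and Syt8, Trim6 and Cysrt1 rose by log2 1.01, 1.18 and 1.43. Lmcd1 fell 2.09-fold (log2 -1.07, SE 0.07; adjusted p = 5.5e-16), as did Chrm3, a muscarinic receptor gene (log2 -1.53, SE 0.12), Tfpi2 (log2 -1.47, SE 0.13) and Lars2 (log2 -0.63, SE 0.05, with uncertain read placement). DESeq2 called 9058 peaks where edgeR called 27281.

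The second comparison asked what PGE2 itself did to the same regions. Peaks of absorptive enterocyte genes were lower with PGE2, 42 of 148 against 5 higher (45 and 5 when adjusted over the list alone; mean log2 change -0.19, SD 0.37), and at 14 of 22 genes the called peaks were all lower. The list passed camera (adjusted p = 1.03e-05), and had adjusted p = 0.282 with an estimated correlation. A peak 14676 bp from Fabp1, the fatty acid binding protein of enterocytes (chromosome 6, 71184736 to 71185670), fell 1.96-fold, from 19.6 ± 0.16 to 9.97 ± 0.14 CPM (log2 -0.97, SE 0.11; adjusted p = 5.06e-09, edgeR). Of Vil1, a microvillus protein gene, 1 of 9 peaks fell (log2 -0.66, SE 0.1), and of the brush border protease gene Mep1a 1 of 6 (log2 -0.46, SE 0.07). Sis had 4 of 8 peaks lower and the transcription factor gene Hnf4g 5 of 12. PPAR targets and fatty acid oxidation genes had 30 peaks lower and 17 higher of 144 (37 and 19 over the list alone), which passed camera (adjusted p = 0.0207), with adjusted p = 0.282 with an estimated correlation. The gene-end peak of Pdk4, a kinase that restrains glucose oxidation (log2 -1.11, SE 0.14), fell. The PPAR call was lost without PGE2 replicate 1 (adjusted p = 0.0545) and with assignment within 10 kb (adjusted p = 0.508), and turned direction on gene-end peaks only (adjusted p = 0.932).

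The fetal and regenerative list also rose with PGE2, with 51 peaks higher and 5 lower of 163 (53 and 9 when adjusted over the list alone; mean log2 change 0.27, SD 0.56). It passed camera (adjusted p = 0.00118) with adjusted p = 0.282 with an estimated correlation, and without PGE2 replicate 1 it did not pass (adjusted p = 0.0711). The Msln peak rose 3.92-fold (log2 1.97, SE 0.15; adjusted p = 1.01e-12, edgeR). Anxa1 again had 8 of 11 peaks higher. In the stem cell list 30 peaks were higher and 35 lower of 261 (30 and 35 over the list alone; adjusted p = 0.261). All 8 peaks of Olfm4 were lower, by log2 -1.17 (SE 0.13) at chromosome 14, 80039587 to 80040510, and Aqp4 was lower (log2 -0.80, SE 0.11), while a gene-end peak of Cdca7 was higher (log2 0.73, SE 0.09).

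YAP and TEAD targets had 33 peaks higher and 12 lower of 163 with PGE2 (adjusted p = 0.261, camera), including Ptpn14 (log2 1.29, SE 0.14), Ajuba (log2 0.62, SE 0.08) and, lower, Crim1 (log2 -0.54, SE 0.07). Wnt targets had 27 higher and 16 lower of 185 (adjusted p = 0.818), including Ccnd1 (log2 0.65, SE 0.08), Sp5 (log2 0.78, SE 0.1) and, lower, Sox9 (log2 -0.40, SE 0.08). The cAMP and CREB targets had 17 higher and 27 lower of 124 (adjusted p = 0.534). Among them Dusp1, a phosphatase gene, rose (log2 0.65, SE 0.07), and Fosb (log2 -0.84, SE 0.08) and Fos (log2 -0.81, SE 0.1) fell. Eicosanoid genes had 24 higher and 22 lower of 169 (adjusted p = 0.891), with Abcc4 at log2 0.85 (SE 0.11), Lta4h at 0.56 (SE 0.08) and 1 peak of the prostaglandin carrier gene Slco2a1 at 1.29 (SE 0.17), a gene with 2 peaks higher and 6 lower of 16 (median log2 -0.18). Cdca7, Ptpn14 and Sox9 each had 1 peak higher and 1 lower with PGE2, Dusp1 2 and 1 of 5 and Fosb 1 and 3 of 8. Adjusted over the list alone, these 4 lists gave 33 and 12, 27 and 10, 18 and 31, and 25 and 22. Of the remaining lists, proliferation genes had 15 higher and 1 lower of 51 (15 and 2 over the list alone; adjusted p = 0.0835) and identity transcription factors 17 and 31 of 195 (17 and 33 over the list alone; 0.0835), and neither passed camera. Both passed fry, the test against no change (adjusted p = 0.0382, higher, and 0.0435, lower). So did YAP targets (0.013, higher) and stem cell genes (0.0435, lower). Stromal, immune and endothelial markers had 2 and 1, 2 and 1, and 6 and 4 peaks higher and lower (0 and 0, 0 and 0, and 6 and 4 over the list alone; adjusted p = 0.539, 0.904 and 0.818). The other lists had adjusted p-values from 0.464 for tuft cells and for immediate early genes to 0.974 for NF-kB and epithelial defence genes.

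**Figure D2:**
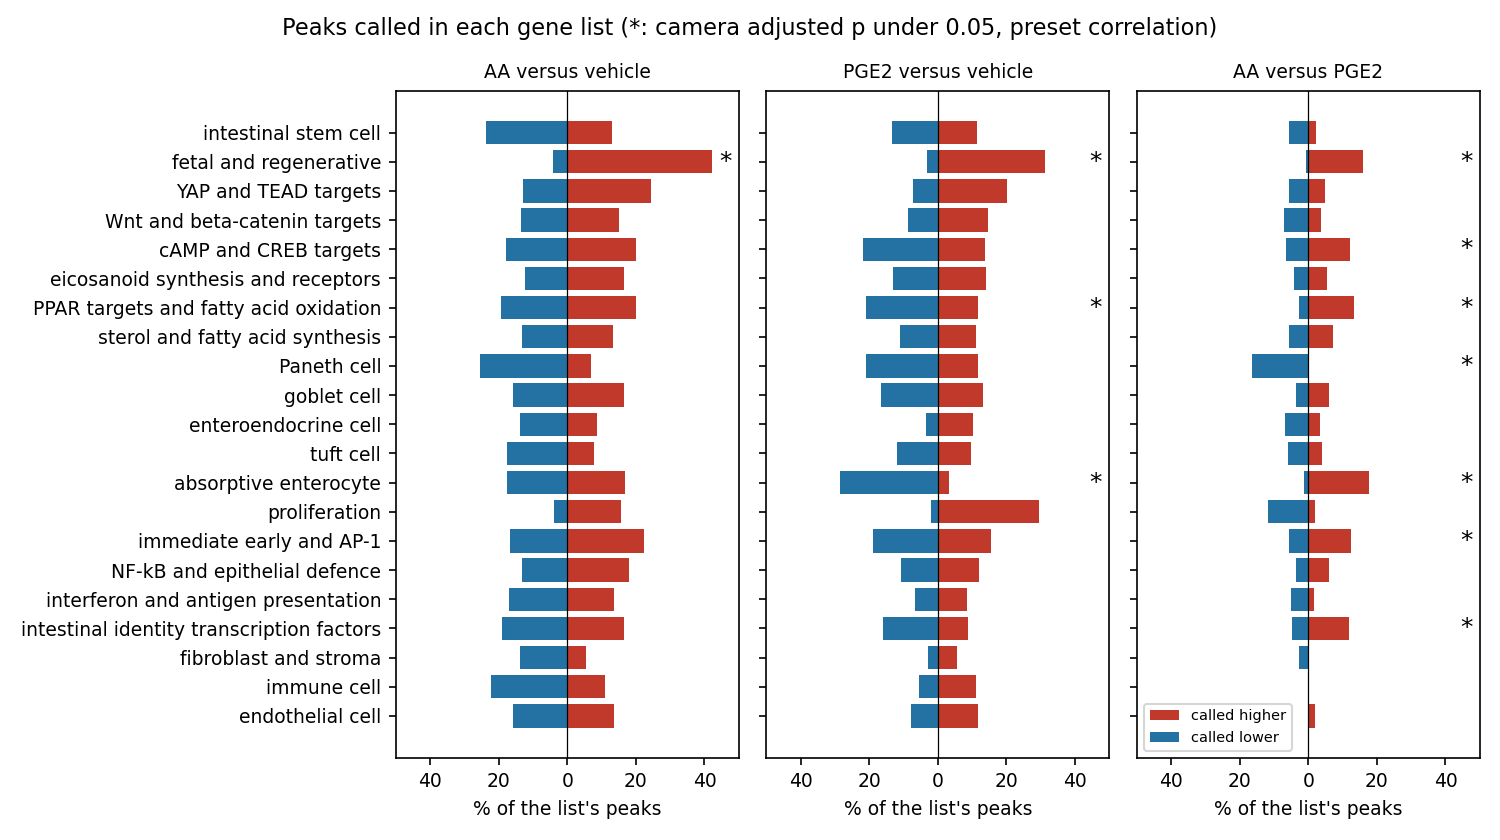
Tested peaks called higher (right of 0) and lower (left of 0) per gene list, in percent of the list's peaks on the x axis, for AA and PGE2 against vehicle and for AA against PGE2. Asterisks mark lists that passed camera with the preset correlation, the 1 list under AA, the 3 under PGE2 and the 7 between them. With an estimated correlation, which leaves at most the 3 degrees of freedom of the fit, 0 passed. Some genes are in several lists.

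In all, PGE2 raised 12809 peaks and lowered 9448 (24.9% of those tested; edgeR quasi-likelihood), of which 2491 and 1331 changed at least 2-fold. With library totals as the scaling the larger side turned (11530 higher and 12121 lower). The largest gains lay in Hmgcll1 (6.41-fold, log2 2.68, SE 0.29), Kcnu1 and Prkg2, at the gene end of Col4a2, a basement membrane collagen gene whose neighbour Col4a1 holds the peak (6.4-fold, SE 0.34), and near Runx2, Prss47, Rnf138 and Elk3 (log2 2.17, SE 0.2). They started from low signal, with vehicle means from 0.535 CPM for Prss47 to 1.72 CPM for Elk3. The largest losses lay near Cp, the ceruloplasmin gene (log2 -2.09, SE 0.29), Vit, Tmem64 (log2 -1.85, SE 0.16), Unc93a, Stc2 (log2 -1.83, SE 0.15), Spag6, Gm5724 and Rnf180. Gene-end peaks of Zfp131 (log2 1.01, SE 0.07), Clk3 (log2 1.10, SE 0.08), Pdia3 (log2 0.96, SE 0.07) and Stt3b (log2 1.16, SE 0.07) rose, the last from 36.4 ± 0.77 to 81.6 ± 8.4 CPM. Those of Lmcd1 (log2 -1.05, SE 0.07), Jun (log2 -1.22, SE 0.1), Fosb and Ugt1a1 (log2 -0.58, SE 0.05, a locus of overlapping genes) fell. Of the peaks called higher, 39% were gene-end peaks, against 14.5% of the other tested peaks (Fisher's exact test, odds ratio 3.76, 95% interval 3.61 to 3.92, over peaks that are not independent replicates). With gene-end and other peaks scaled separately, a setting chosen after seeing the data, they were 25.4% and 16.8% (odds ratio 1.68, 95% interval 1.61 to 1.76). They were then also 31.4% of the peaks called lower (9.5% before, against 19% of the others). Gene-end peaks are centred by such scaling, which by itself raises their share of the lower peaks. With AA they were 15.8% of the higher peaks, against 18.5% of the others, and 20.1% without PGE2 replicate 1 or without PGE2 replicate 2; of the lower peaks they were 10.6%. Gene-end peaks held 34.86% and 34.35% of the counts in vehicle, 35.29% and 35.8% with AA and 37.37% and 38.9% with PGE2. DESeq2 called 7377 peaks for PGE2, and edgeR called 14246 without vehicle replicate 1 and 13667 without vehicle replicate 2, against 22257 with both.

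**Figure D3:**
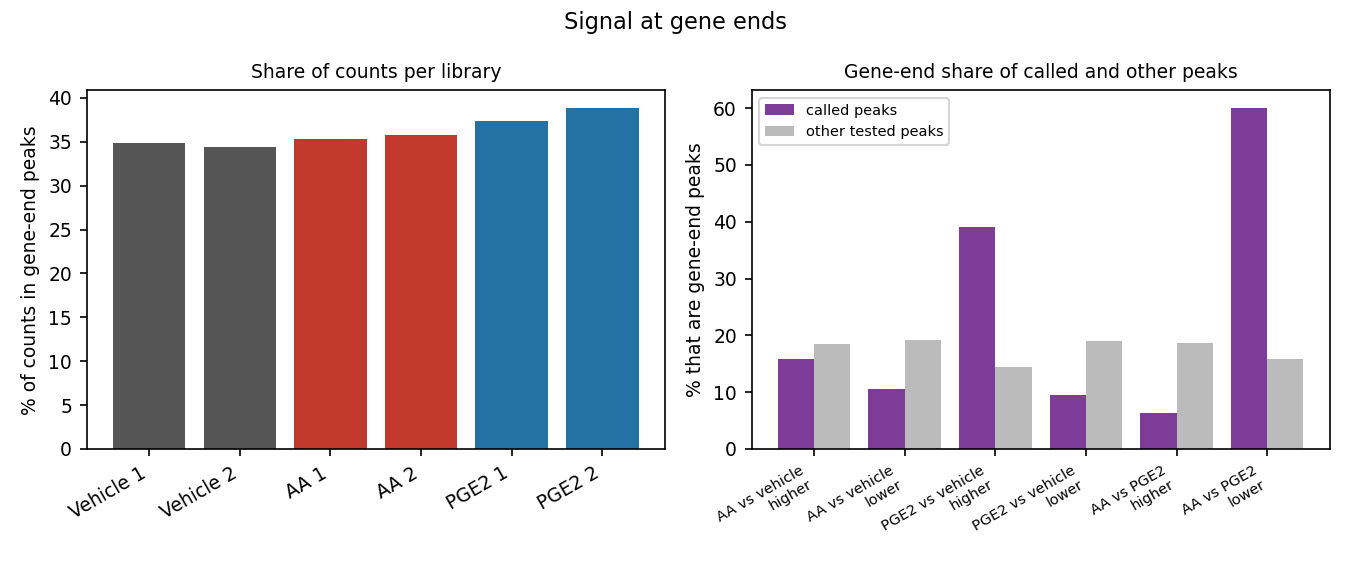
Share of counts in gene-end peaks per library (left, bars in percent) and percent of called peaks and of other tested peaks that are gene-end peaks, per comparison and direction (right). The PGE2 libraries lie at 37.37% and 38.9% and the other 4 between 34.35% and 35.8%, and 39% of the peaks called higher with PGE2 are gene-end peaks.

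Both treatments were compared with the same vehicle libraries. Their log2 changes correlated across peaks, which are not independent replicates, at r = 0.783 and rho = 0.758. Simulated unchanged groups, with all libraries drawn anew and the simulated vehicle libraries shared as controls, gave 0.501 and 0.465 (10 simulations). They show what sharing controls gives in general, not what these vehicle libraries contributed. The covariance was 0.216 against 0.0302 simulated, a difference of 0.186. At 8028 peaks both treatments were higher and at 6633 both lower, where independent lists would share 2138 and 1308, values that leave out the shared controls. Opposite calls were made at 27 peaks, against 3350. Part of this excess may come from the shared controls. Signs matched at 79.1% of the peaks, against 66.7% simulated. With vehicle replicate 1 as the control for AA and replicate 2 for PGE2, a split chosen after seeing the data that leaves 1 control library each, r was 0.574, the covariance 0.182 and the match of signs 70.5%. With the libraries exchanged the values were 0.615, 0.191 and 72.5%. Counts of calls are left out here, because 1 control library gives no spread of its own. Examples changed by both were Lmcd1, Olfm4, Msln and Runx2, the last from a low vehicle mean of 0.573 CPM.

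**Figure D4:**
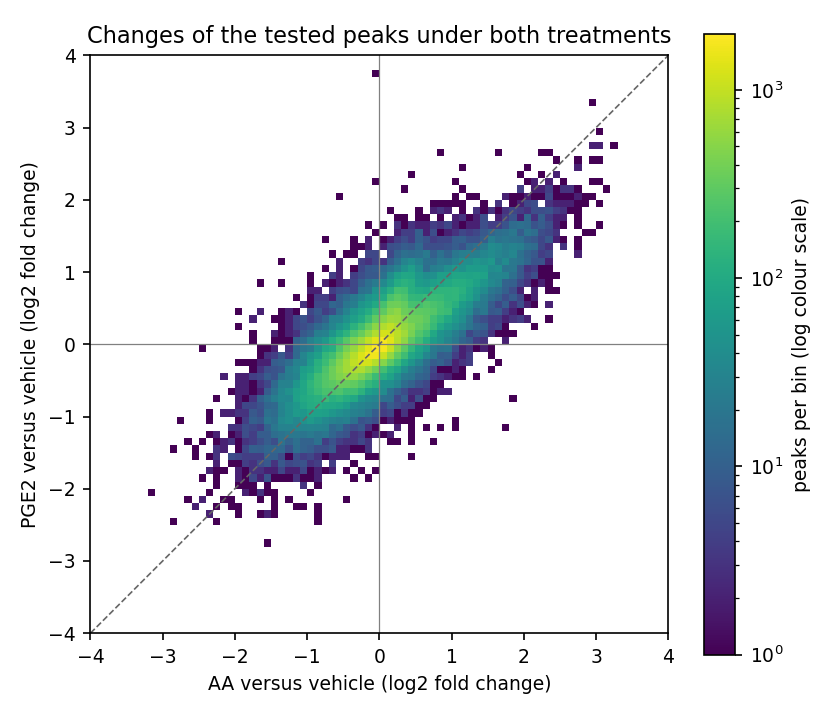
Density of 89346 tested peaks by log2 change with AA (x axis) and with PGE2 (y axis) against vehicle, in bins of 0.1, with colour on a log scale for the number of peaks. Most peaks lie along the rising diagonal (r = 0.783); 1 peak lies outside the axes.

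The third comparison set AA at 25 µM directly against PGE2 at 50 nM, doses that differ, and asked where the fatty acid and the prostaglandin parted. Enterocyte genes were higher with AA than with PGE2, 26 peaks against 2 lower of 148 (30 and 2 when adjusted over the list alone; camera adjusted p = 3.04e-06, and adjusted p = 0.208 with an estimated correlation). On gene-end peaks only the list did not pass (adjusted p = 0.283). A peak inside Hnf4g (chromosome 3, 3640055 to 3640997) was 2.2-fold higher with AA (log2 1.13, SE 0.17), the Fabp1 peak 1.65-fold (log2 0.72, SE 0.11) and a peak inside Rbp2, a retinol binding protein gene, 1.28-fold (log2 0.36, SE 0.06). The fetal and regenerative list was higher with AA at 26 peaks and lower at 1 of 163 (28 and 2 over the list alone; adjusted p = 3.04e-06, and adjusted p = 0.139 with an estimated correlation), with Il1rn at log2 0.73 (SE 0.11) and Plaur, the urokinase receptor gene, at 0.42 (SE 0.07). PPAR targets were higher at 19 peaks and lower at 4 of 144 (22 and 5 over the list alone; adjusted p = 0.00396, and adjusted p = 0.208 with an estimated correlation). They did not pass with assignment within 10 kb (adjusted p = 0.11) or on gene-end peaks only (0.406). Among the PPAR targets the gene-end peak of Pdk4 was 2.55-fold higher (log2 1.35, SE 0.13; adjusted p = 1.63e-08, edgeR) and a peak near Pparg 1.24-fold (log2 0.31, SE 0.06).

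Paneth cell genes were lower with AA than with PGE2 at 7 of 43 peaks (7 over the list alone; camera adjusted p = 0.00519, and adjusted p = 0.227 with an estimated correlation). The list did not pass with fry, which tests against no change rather than against other peaks (adjusted p = 0.0581), or on gene-end peaks only (0.479). Its lower peaks included Dll4, a Notch ligand gene (log2 -0.46, SE 0.1), Wnt3 (log2 -0.39, SE 0.1) and Itln1 (log2 -1.02, SE 0.28). The edgeR call at Dll4 was lost without AA replicate 1 (log2 -0.39), and those at Wnt3 and Itln1 without AA replicate 2 (-0.30 and -0.76) or PGE2 replicate 2 (-0.27 and -0.75). A further 3 lists passed, all with adjusted p = 0.208 with an estimated correlation. They overlap with each other or with other lists. Fos, Fosb, Atf3 and Dusp1 are in both the AP-1 and the CREB list. Areg, also a YAP target, gave 5 of the 15 higher CREB peaks, and Hnf4g, also an enterocyte gene, 6 of the 23 higher identity peaks. Immediate early and AP-1 genes had 18 higher and 8 lower of 143 (20 and 8 over the list alone; adjusted p = 0.0104), with Ier3 (log2 0.46, SE 0.08), Klf6 (log2 0.31, SE 0.06) and, lower, the gene-end peak of Dusp1 (log2 -0.34, SE 0.07; not called without AA replicate 1, -0.27). Dusp1 had 1 peak higher and 1 lower of 5, with a median log2 of 0.58. The cAMP and CREB targets had 15 and 8 of 124 (22 and 10 over the list alone; adjusted p = 0.0256), with Areg (log2 1.30, SE 0.15), Ppargc1a (log2 0.54, SE 0.1) and, lower, Nr4a2 (log2 -0.64, SE 0.11). Without PGE2 replicate 1 both of these lists had adjusted p = 0.148. The AP-1 list also did not pass within 10 kb (adjusted p = 0.0587), with fry (0.0581) or on gene-end peaks only (0.863). Nor did the CREB list within 10 kb (0.234), on gene-end peaks only (0.883) or, a setting chosen after seeing the data, without gene-end peaks (0.0686). Identity transcription factors had 23 and 9 of 195 (29 and 11 over the list alone; adjusted p = 0.027), with Isx (log2 0.56, SE 0.06), Hnf4g and Gata4 (log2 0.43, SE 0.07). Without AA replicate 2 or PGE2 replicate 2 they had adjusted p = 0.0539 and 0.0561, within 10 kb 0.0583, on gene-end peaks only 0.901 and, chosen after seeing the data, without gene-end peaks 0.136.

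Stem cell genes had 6 peaks higher and 15 lower with AA than with PGE2 of 261 (5 and 15 over the list alone; adjusted p = 0.125), with Cd44 (log2 0.49, SE 0.07), Sox9 (log2 -0.41, SE 0.08) and Rgmb (log2 -0.28, SE 0.06; not called without AA replicate 1, -0.23). YAP targets had 8 and 9 of 163 (9 and 10 over the list alone; adjusted p = 0.939), with Asap1 (log2 0.48, SE 0.09) and Tgfb2 (log2 -0.63, SE 0.15). The Tgfb2 call was lost without AA replicate 1 (-0.62) or PGE2 replicate 2 (-0.54). Wnt targets had 7 and 13 of 185 (7 and 15 over the list alone; adjusted p = 0.149), with Sp5 (log2 -0.59, SE 0.1) and Lgr4 (log2 0.46, SE 0.09). Eicosanoid genes had 9 and 7 of 169 (9 and 7 over the list alone; adjusted p = 0.858), with Cbr1 (log2 0.39, SE 0.07), Slco2a1 (log2 1.00, SE 0.2) and a gene-end peak of Abcc4 (log2 -0.63, SE 0.1), which had 1 peak higher and 3 lower of 27. The remaining lists did not pass camera, with adjusted p-values from 0.067 for proliferation genes (6 lower and 1 higher of 51; 8 and 1 over the list alone) to 0.939. With fry, the test against no change, stem cell, Wnt target and enteroendocrine genes passed, each lower with AA (adjusted p = 0.0354).

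Between the treatments 4523 peaks were higher with AA and 4363 higher with PGE2 (9.9% of those tested; edgeR quasi-likelihood), of which 335 and 304 differed at least 2-fold. The largest differences toward AA lay near Ckap2l (3.3-fold, log2 1.72, SE 0.3), Dusp10 (3.19-fold, SE 0.28), Copb1, Il1f10 (2.97-fold, SE 0.23), 4930558K02Rik, Ric8b, Azgp1 and Itpr2. Their PGE2 means were low, from 1.04 CPM for Ckap2l to 2.34 CPM for Azgp1. Toward PGE2 the largest differences lay at Fam168b (log2 -1.63, SE 0.31), Gas1 (log2 -1.63, SE 0.28), Gm13288 (a locus of similar gene copies), Galnt9, Rragd, Hcn4 and Kcnma1, and 16623 bp from Psme4. Calls were lost at Fam168b (log2 -1.15) and Hcn4 (-1.06) without PGE2 replicate 2, at Psme4 (-1.37) and Kcnma1 (-1.75) without AA replicate 1, and at Kcnma1 (-1.22) without AA replicate 2. Gene-end peaks higher with AA were those of Pdk4, Gpr137c (log2 1.23, SE 0.12), Isx and Areg, and those higher with PGE2 were Zfp131 (log2 -0.62, SE 0.07), Zfp664 (log2 -0.84, SE 0.09), Ube2d2a (log2 -0.89, SE 0.1) and Gab1 (log2 -0.66, SE 0.08). Gene-end peaks made up 60.1% of the peaks higher with PGE2, against 15.9% of the others (Fisher's exact test, odds ratio 7.97, 95% interval 7.48 to 8.5), and 6.3% of those higher with AA. With gene-end and other peaks scaled separately, a setting chosen after seeing the data, these shares were 40.9% and 25%, values that such centring sets in part. DESeq2 called 582 peaks, and edgeR called 3072 without AA replicate 1, 4029 without AA replicate 2 and 5629 without PGE2 replicate 2, against 8886 with all libraries. The larger side turned toward PGE2 without PGE2 replicate 1 and without AA replicate 2. It also turned with limma-voom (4128 higher with AA and 4481 with PGE2), with DESeq2 (229 and 353), at adjusted p under 0.01 (1987 and 2005) and with a replicate block.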

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

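All tests of explanations in this part were chosen after the results were seen.

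AA and PGE2 were called in opposite directions against vehicle at 27 peaks (edgeR quasi-likelihood test), 0 of which DESeq2 called in both comparisons. AA was higher and PGE2 lower than vehicle at 18 of them, 1 of which was a gene-end peak, and the reverse held at 9, of which 6 were gene-end peaks. A peak flanking Pdk4 (chromosome 6, 5509418 to 5510283) changed by log2 0.38 (SE 0.11) with AA and by -0.80 (SE 0.13) with PGE2, a difference of 1.19 (adjusted p = 3.4e-08, edgeR). A gene-end peak of Fads1, a desaturase gene of the pathway that makes AA (chromosome 19, 10182450 to 10183923), changed by log2 -0.24 (SE 0.09) with AA and by 0.35 (SE 0.08) with PGE2, a difference of -0.59 (adjusted p = 1.51e-05, edgeR). Peaks near Isx (0.47 and -0.22), Lgals3 (0.23 and -0.17), Zc3h12a (0.36 and -0.40) and Tm4sf20 (0.36 and -0.41) went up with AA and down with PGE2. All 27 peaks passed edgeR between AA and PGE2, which calls in opposite directions nearly require. The p-values of that difference therefore add no support. Some calls against vehicle lay near the threshold, such as Fads1 with AA (adjusted p = 0.037, edgeR) and Isx with PGE2 (0.0496). The absorptive enterocyte list differed between the treatments as well (camera, adjusted p = 3.04e-06, and adjusted p = 0.208 with an estimated correlation).

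Gene-end peaks were higher in the PGE2 libraries than in the others. A difference in depth would have put their share of counts in the PGE2 libraries between those of the AA libraries, as the totals are, yet the lowest PGE2 share lay 1.57 percentage points above the highest AA share. One common factor for all gene-end peaks cannot be told apart from changes of single peaks: after separate scaling 3263 gene-end peaks were called higher and 3073 lower, a ratio of 1.06, but such scaling centres these peaks and so evens the split by itself. An axis of gene-end signal that also differs between libraries of one group remains a candidate explanation: across 10916 gene-end peaks, the difference between the 2 PGE2 libraries correlated with the PGE2 change at 0.59, against -0.18 in vehicle and 0.26 in AA. An effect of PGE2 stays open and was not separated from this axis, and base composition was not tested.

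The fetal and regenerative list was higher in the AA libraries. Stromal, immune or endothelial cells would have raised their own markers, but the mean log2 change of the 105 peaks of those 3 lists was -0.12 (SE 0.055), just over 2 SE below 0. This SE treats peaks as independent, though 16 are of Pecam1, so it is too small. In camera the lists had adjusted p = 0.306, 0.805 and 0.805. In fry, the test against no change, they had adjusted p = 0.0497, 0.238 and 0.222, each toward lower. These values show no common rise and do not establish a fall. The lists share 0 genes with the fetal list, and the epithelial sort would remove such cells. Their peaks with the highest signal were at Acta2 (47.8 CPM with AA against 45.8 in vehicle, log2 0.06, adjusted p = 0.519), Tek (32.4 against 25.4, log2 0.34), which alone passed edgeR (adjusted p = 0.00182), and Pecam1 (20.5 against 22.2, log2 -0.11, adjusted p = 0.411). The shift of signal toward gene ends is excluded as the whole cause only under camera's preset correlation, with which the list still passed without gene-end peaks (adjusted p = 2.68e-07); over all peaks it had adjusted p = 0.0783 with an estimated correlation. An effect of AA and a bias of base composition both stay open.

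The absorptive enterocyte list was lower in the PGE2 libraries. The shift toward gene ends is excluded as the whole cause only under camera's preset correlation, with which the list passed without gene-end peaks (adjusted p = 0.000911); over all peaks it had adjusted p = 0.282 with an estimated correlation. A smaller share of absorptive cells cannot be told apart from closing within such cells: the means of the 4 secretory lists, goblet (0.05, SE 0.04), Paneth (0.04, SE 0.08), enteroendocrine (0, SE 0.06) and tuft (-0.07, SE 0.05), spanned 0.12, with an SE of the difference of 0.06. That spread is too wide to show a common rise or to exclude one. Base composition was not tested here either.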

How the results depend on the processing

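Settings on gene-end scaling, without gene-end peaks, loess offsets for lists, gene span and split controls were chosen after seeing the data. Of 136 named peak results, 113 kept their direction and call in all 19 settings, 23 lost the call in at least 1 and 0 reversed; glmTreat took 20 of these calls, DESeq2 10 and a left-out library up to 6. Peaks called with AA were 18035 at adjusted p under 0.01, 9058 with DESeq2, 14957 with glmTreat against 1.2-fold and 18219 to 30456 with a library left out; with PGE2 they were 14066, 7377, 10310 and 13667 to 21329, and for AA versus PGE2 3992, 582, 1023 and 3072 to 9643. The cause was not tested. Fewer libraries leave fewer degrees of freedom, yet AA gave 30618 calls with only the 4 libraries compared, against 27281 with all 6. Degrees of freedom alone therefore do not account for the counts with AA. With library totals, calls were 13732 higher and 14316 lower for AA and 11530 and 12121 for PGE2, so that the larger side turned. Gene lists passing under AA were 2 within 10 kb, 0 with an estimated correlation, 5 with fry, 2 with loess offsets, 2 by gene span and 1 to 3 with a library left out; under PGE2 they were 0 with an estimated correlation, 7 with fry and 1 to 3, and for AA versus PGE2 0 with an estimated correlation. Of 11 list results, 3 kept their call in all 13 settings of camera with the preset correlation: fetal and regenerative genes under AA (1.09e-10 to 2.68e-07) and for AA versus PGE2 (1.2e-06 to 0.00406), and enterocyte genes under PGE2 (2.03e-06 to 0.00325). The other 8 lost it in 1 to 5. Fry, which tests against no change and not against other peaks, gave these 3 adjusted p = 0.00231, 0.0251 and 0.0297. PPAR targets under PGE2 turned direction on gene-end peaks only (adjusted p = 0.932). The correlation of the treatments was 0.713 to 0.811 with a library left out, and 0.574 and 0.615 with 1 vehicle library for each treatment. The gene-end share of peaks higher with AA was 10.8% to 20.1% with a library left out, and turned above that of other peaks without PGE2 replicate 1 or PGE2 replicate 2 (20.1% in both). With separate scaling that of peaks lower with PGE2 was 31.4% (9.5% before) and of peaks higher with AA than PGE2 25%, both turned by the scaling itself. Deviations of replicate 1 from the group mean hardly correlated between groups (0.005, -0.02 and 0.036). This cannot exclude that replicate numbers pair the libraries. Vehicle and AA libraries differed little beyond counting noise (chi-square per degree of freedom 1.1 and 1.12), which pulls such correlations toward 0. A replicate block gave 27630, 22672 and 9414 peaks, the last with 4604 higher with AA and 4810 with PGE2, so that the larger side turned. List medians changed sign between scalings only for lists that did not pass. Corrections for base composition, alone or with the block, and motif tests were not run for want of a genome sequence here. Of simulated 1.5-fold changes, 22% to 28% were recovered, with only 200 peaks changed, so this is not the sensitivity in the data.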

Other observations

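The values in this part were chosen after the results were seen, and no test of a cause was run on them. Some loci changed along most of their peaks. With at least 6 peaks called one way, 0 the other way and at least 75% called, edgeR's calls gave 13 such genes higher and 11 lower with AA, and 4 higher and 4 lower with PGE2. All 9 peaks of Tekt3 were higher with AA (median log2 change 0.89) and 8 of 9 with PGE2 (0.43). Ggta1 and Ccdc71l each had 9 of 10 peaks higher with AA, and Itgav, an integrin gene, 6 of 8. DESeq2 called fewer peaks higher, 7 with AA and 2 with PGE2 at Tekt3 and, with AA, 2 at Ggta1, 7 at Ccdc71l and 2 at Itgav. All 6 peaks of Cldn18, a tight junction gene known from stomach and lung, were higher with PGE2 (median log2 1.13) and 5 of 6 with AA (1.36), with 5 and 4 called by DESeq2. With AA, all 6 peaks of the cadherin gene Cdh26, 10 of 11 of Epb41l3, 9 of 10 of Bmp7, a growth factor gene, and 7 of 8 each of the nuclear receptor gene Esrrg and the organic cation transporter gene Slc22a3 were lower. DESeq2 called 4 peaks lower at Cdh26, 5 at Epb41l3, 2 each at Bmp7 and Esrrg and 0 at Slc22a3. With PGE2 9 of 11 peaks of Epb41l3 (median log2 -0.52), 6 of 8 of Esrrg (-1.05) and 6 of 8 of Slc22a3 (-0.80) were lower too (4, 3 and 0 with DESeq2).

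The 2 desaturase genes of the pathway that makes AA had peaks lower with AA by edgeR's test, 4 of 6 at Fads1 (median log2 -0.74) and 4 of 5 at Fads2 (median -0.46), while DESeq2 called 3 and 1. With PGE2 Fads1 had 2 peaks lower and 1 higher, and Fads2 1 lower. In the direct comparison, 3 of the Fads1 peaks and 1 of the Fads2 peaks were lower with AA than with PGE2 (1 and 0 with DESeq2). At Isx, 8 of 10 peaks were higher with AA and 6 were higher with AA than with PGE2 (5 and 5 with DESeq2), while PGE2 against vehicle gave 2 higher and 1 lower (0 with DESeq2).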
